A study of Thalassiosira oceanica CCMP1005 with 6 samples.

How the data were processed

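Messenger RNA abundance was measured by Illumina sequencing in 6 libraries of the oceanic centric diatom Thalassiosira oceanica CCMP1005, a single-celled marine alga. The libraries fall into 2 lines of 3 replicates each, which the labels call CCuA and LCuA. Per the labels' protocols, cells were collected on filters, total RNA was extracted with a DNase step, and poly(A) RNA was taken from 1 ug of total RNA with an integrity number of at least 6.5 and made into fragmented cDNA libraries. Poly(A) selection leaves out most ribosomal RNA and most organellar and bacterial transcripts, so plastid-encoded and mitochondrion-encoded genes are measured poorly, if at all, by this assay.

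The authors deposited a table of estimated counts for 22678 genes in the 6 libraries, given as whole numbers and not normalized. Per the file headers, the features carry the identifiers that the Trinity assembler writes, so each gene is a group of assembled transcripts and not a locus of a reference genome. Trimmomatic 0.36 and RSEM appear in the submitters' processing notes, without a stated role. Between 33 and 66 genes per LCuA library had a count of 0 but an RPKM above 0, so the deposited counts are estimates rounded to whole numbers. The aligner, the assembler's version, the filters and the use of strand are not given in the sources used here. Reads that match several assembled genes can be divided among them by such estimates, which affects genes with near-identical copies. Of the 22678 genes, 15007 were alone in their assembly component and 7671 shared one of the 17601 components with at least 1 other gene. Such sister genes can be fragments, alleles or paralogs, and their separate counts are uncertain to that extent.

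The authors also deposited a table of RPKM values for the same genes. Its 3 LCuA columns were used only to recover a length per gene, from libraries with at least 10 reads for the gene. The recovered lengths differed little between libraries, with a median ratio of longest to shortest of 1.01. The other 3 columns of that table bear a name that no label gives and were not used. The planned comparisons on log2 RPKM values were therefore not made.

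Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default filterByExpr filter by group, a model with the line as its only term and 4 residual degrees of freedom, and Benjamini-Hochberg adjustment over the 17866 genes tested. A gene was called at an adjusted p under 0.05, and a second count required a fold change of at least 2. Log2 fold changes are LCuA minus CCuA. CPM values are the counts scaled to a common library size with the TMM factors. Log2 CPM values for correlations and principal components used a prior count of 2. On simulated data for this comparison, drawn for 17866 genes from the real means, library sizes and dispersions with 50 genes changed at each of 4 fold sizes, the test recovered 4% of genes changed 1.5-fold, 22% of those changed 2-fold, 80% of those changed 4-fold and 94% of those changed 8-fold, and 4.76% of its calls were false. The simulation made 105 calls, so its threshold after adjustment was stricter than in the real data. The changed genes were drawn only from those above a minimum mean count, so the recovery rates leave out genes with few reads. Neither these rates nor the false share, which rests on 5 false calls, carry over to the real comparison.

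Genes with reads in one line only were defined as genes with at least 10 reads in each of the 3 libraries of one line and 0 in all 3 of the other. A count of 0 allows up to 3 reads in a library, and such floors cover counting error only. Concentration of reads was compared with a two-sided exact permutation test, for which the smallest possible p is 0.1. Alternatives covered the scaling, the filter on low counts, the replicate number as a block, DESeq2 1.42.0, limma-voom (limma 3.58.1), a stricter threshold, a test against a 2-fold change and leaving out each library in turn.

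The design, the tests, the rule for named genes and the alternatives were set before the data were examined, except where a later choice is stated. The rule named genes with an adjusted p under 0.05, a mean of at least 10 CPM in the higher line and replicates that did not overlap between lines. The 2 largest rises and the 2 largest falls among them are named. The parts of the rule that need gene descriptions did not apply, because the deposited tables do not pair the identifiers with gene names. For the same reason the 25 functional gene lists set in advance, among them copper transport, plastocyanin and other copper proteins, respiration, light harvesting and iron uptake, were not analysed here. The expression classes and the fold-size classes were chosen after seeing the data.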

Results

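The transcriptomes of 2 lines of Thalassiosira oceanica with different copper histories were compared. The CCuA line had been kept at sufficient copper for 3600 generations, and the LCuA line had been kept under copper deficiency for 2250 generations. Per the labels' protocols, both lines were then grown at 1 nM copper in Aquil, a synthetic seawater medium, at 20 °C under continuous light of 200 umol photons per square metre per second. The cell type label, however, names only copper-sufficient medium for CCuA. It is read here as the line's history and the protocol as the medium of the sampled cells, but the labels do not settle this. If that reading is wrong, differences between the lines would include the direct response to a difference in medium. If it is right, CCuA had been moved from sufficient copper to 1 nM copper. A response to that move cannot be told apart from the line's history. The comparison addresses which transcript levels differ between these 2 lines. Differences that arose for reasons other than copper while the lines were kept apart cannot be told apart from an effect of copper history. Copper is a cofactor of plastocyanin, which carries electrons in photosynthesis in this diatom, and of cytochrome c oxidase in respiration. The genes of these proteins were not analysed here, because the deposited identifiers carry no gene names.

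Each line was represented by 3 libraries, and all 22678 assembled genes had at least 1 read in some library. Total estimated counts were 13834351, 12326419 and 13415592 in CCuA replicates 1 to 3 and 13138522, 14635497 and 14764957 in LCuA replicates 1 to 3. Between 21362 and 21670 genes had at least 1 read in a library, and between 17147 and 18043 had at least 10. The labels do not say whether replicates came from separate cultures or from separately evolved populations. The p-values then measure only the spread between these samples, which may be technical, and the lines differ in the number of generations as well as in copper history.

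The libraries separated by line. Across the 17866 tested genes, which are not independent replicates, the Pearson correlation of log2 CPM was 0.973 to 0.977 between CCuA libraries, 0.953 to 0.972 between LCuA libraries and 0.874 to 0.900 between lines. The first principal component held 68.1% of the variance and placed the 3 CCuA libraries at -78.7 to -67.8 and the 3 LCuA libraries at 67.5 to 81.6. The second component held 12.6% and set LCuA replicate 1, at 59.4, apart from LCuA replicates 2 and 3, at -22.1 and -43.2. Replicates were not duplicates of one library, since counts of every pair within a line varied at least 17.8 times as much as sampling noise in a chi-square statistic per degree of freedom. The LCuA libraries differed more among themselves than the CCuA libraries did. The common biological coefficient of variation estimated by edgeR was 28.9% within LCuA and 18.9% within CCuA, and 22.5% within LCuA without replicate 1. This difference was not tested.

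**Figure D1:**
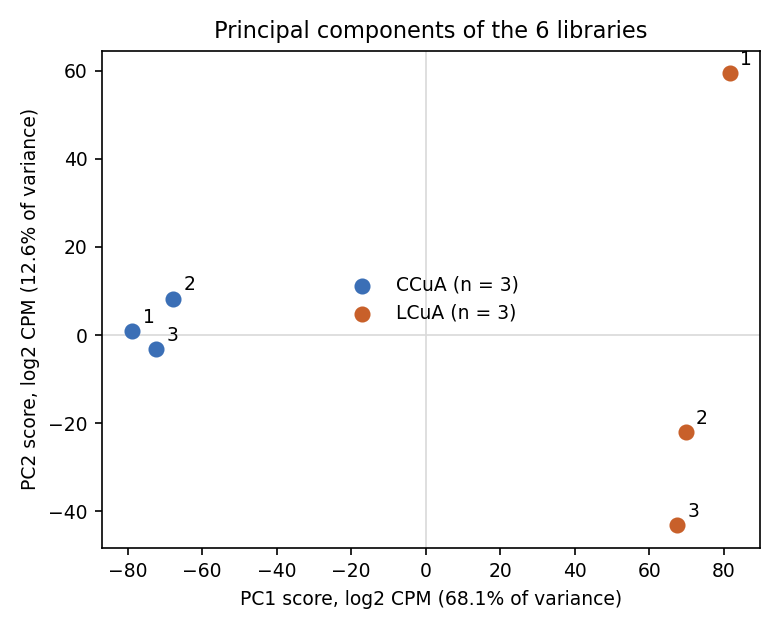
Scores of the 6 libraries on the first and second principal components of log2 CPM; each point is a library, coloured by line and numbered by replicate. The lines lie on opposite sides of the first component, and LCuA replicate 1 lies at 59.4 on the second component while the other LCuA libraries lie at -22.1 and -43.2.

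The lines differed in a large part of the transcriptome, in both directions. In LCuA, 1854 genes were higher and 2273 were lower than in CCuA, together 23.1% of the 17866 genes tested (edgeR quasi-likelihood test, adjusted p under 0.05, n = 3 per line), and 13739 genes were not called. The median change of a called gene was 2.27-fold. A change of at least 2-fold was found for 1191 higher and 1384 lower genes. The genes called higher held 8.03% ± 0.471 (SD, n = 3) of all reads in CCuA and 16.4% ± 0.570 (SD, n = 3) in LCuA, and the genes called lower held 21.8% ± 1.28 (SD, n = 3) in CCuA and 10.3% ± 0.574 (SD, n = 3) in LCuA. These shares describe genes chosen by the test itself and are not independent evidence. Lower genes made up 55.1% of the calls, but with upper-quartile scaling the split was 2105 higher and 2074 lower. The number of calls fell from 4127 to 2603 without CCuA replicate 1, 2725 without CCuA replicate 2 and 2700 without CCuA replicate 3, while 2130 genes, 845 higher and 1285 lower, were called both with all libraries and in each of the 6 fits that left out 1 library.

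The values of the 2 lines did not overlap for 43.5% of the tested genes, where chance gives 10%. At an unadjusted p under 0.05 the edgeR test found 6561 genes.

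**Figure D2:**
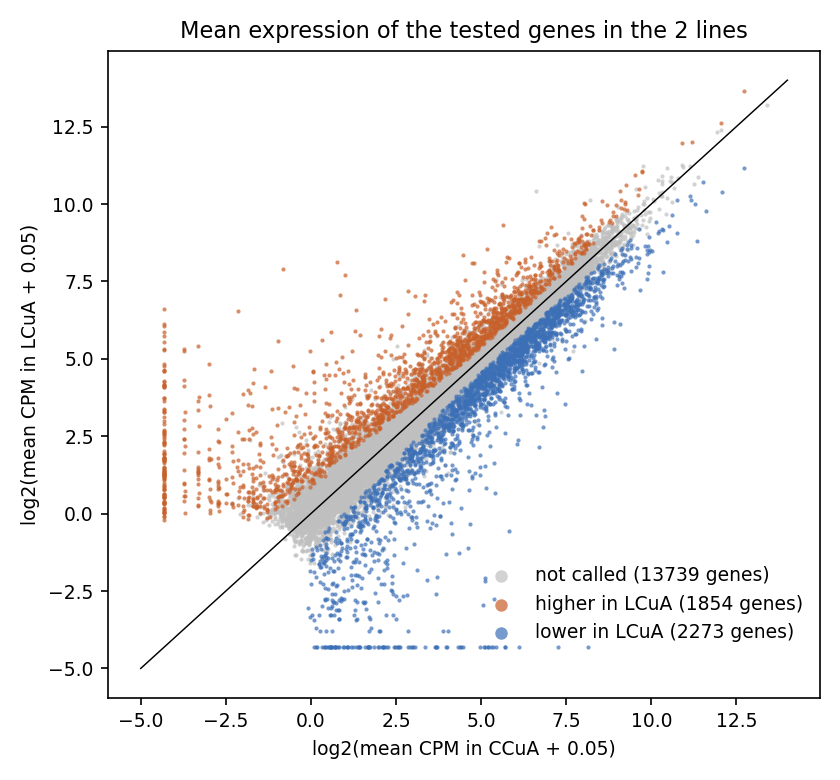
Mean expression of each tested gene in CCuA (x axis) and LCuA (y axis), as log2 of the mean TMM-scaled CPM plus 0.05; each point is a gene, coloured by its call, and the line marks equal expression. Called genes lie on both sides of the line, 1854 above and 2273 below, and the genes in straight rows at the left and lower edges had no or almost no reads in one line.

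Changes reached the most abundant transcripts as well as the rare ones. Among the 2498 genes with a mean over 100 CPM, 255 were higher and 408 were lower in LCuA. Among the 7952 genes at 10 to 100 CPM, 815 were higher and 1134 lower. The 6395 genes at 1 to 10 CPM gave 648 higher and 618 lower calls, and the 1021 genes under 1 CPM gave 136 and 113. The share of lower genes among the calls was thus 45.4% in the rarest class and 61.5% in the most abundant class, and 43.4% and 54.1% in these classes with upper-quartile scaling. The median absolute log2 fold change of called genes was 0.91 over 100 CPM, 1.71 at 1 to 10 CPM and 3.18 under 1 CPM. The calling threshold may set this difference in part, since genes with few reads need a larger change to be called. Every called gene under 1 CPM had a change of at least 2-fold. At 1 to 10 CPM, 569 of the 648 higher and 547 of the 618 lower genes did.

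**Figure D3:**
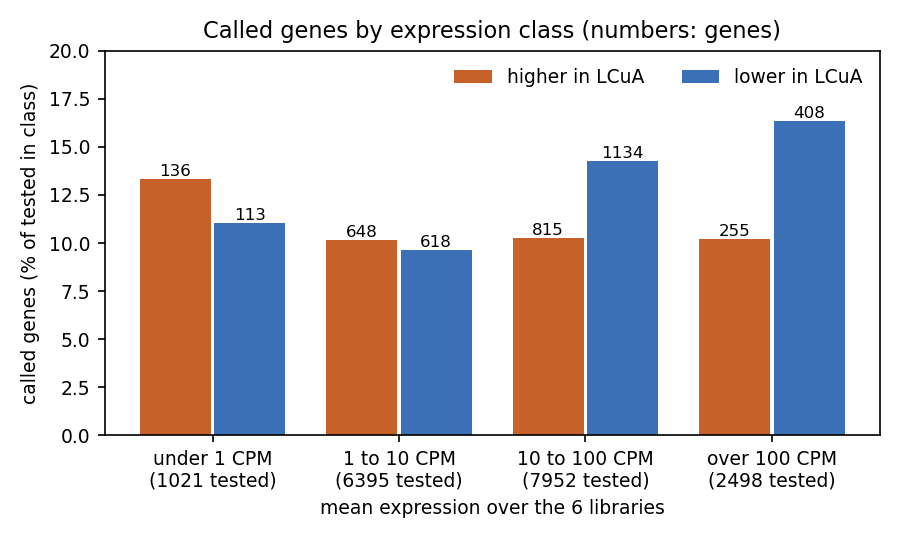
Called genes as a percentage of the tested genes in 4 classes of mean expression (CPM over the 6 libraries); bars show genes higher and lower in LCuA, and the number above each bar is the number of genes. Over 100 CPM there were 408 lower and 255 higher genes, while under 1 CPM there were 113 lower and 136 higher genes.

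Of the 100 most abundant genes, 19 were higher in LCuA, 20 were lower and 61 were not called. The called log2 fold changes in this set ran from -2.53 to 1.52, and 8 of the higher and 14 of the lower genes changed at least 2-fold. Over all 100 genes the highest log2 fold change was 3.81, in a gene that was not called. The reads were not detectably more concentrated in few genes in either line. The 10 most abundant genes of each library held 5.01% ± 0.603 (SD, n = 3) of reads in CCuA and 5.76% ± 0.430 (SD, n = 3) in LCuA (two-sided exact permutation p = 0.2), and the 100 most abundant held 15.7% ± 0.768 (SD, n = 3) and 16.3% ± 0.674 (SD, n = 3; exact permutation p = 0.4). The smallest p that 3 against 3 libraries allow is 0.1.

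Most called changes were moderate, and a small class was extreme. A change under 2-fold was found for 663 higher and 889 lower genes, one of 2-fold to 4-fold for 681 higher and 932 lower genes, and one of 4-fold to 16-fold for 286 higher and 278 lower genes. The fitted change exceeded 16-fold for 224 higher and 174 lower genes. Of these 398 genes, 283 had at most 3 reads in all libraries of the lower line together, so that their fitted fold changes depend on the prior count and give no size.

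Some genes gave reads in one line only. With at least 10 reads in each library of one line and 0 in each library of the other, 115 genes were seen in LCuA alone and 87 in CCuA alone. They were 0.698% of the 16468 genes with at least 10 reads in every LCuA library and 0.534% of the 16291 such genes in CCuA. Of these 202 genes, 198 passed the filter on low counts, and each of the 198 was called by edgeR at an adjusted p under 0.05. Those calls follow from the selection on the same counts and are not independent evidence. Many were far above the detection limit. A mean of over 100 reads per library was reached by 31 of the LCuA-only genes and 27 of the CCuA-only genes, and the largest mean was 1407 reads in LCuA and 3718 reads in CCuA. A count of 0 allows up to 3 reads, or 0.194 to 0.240 CPM depending on the library. Summing the counts of sister genes over each assembly component, an alternative chosen after seeing the data, left 77 components read in LCuA alone and 62 read in CCuA alone.

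The 2 largest rises and the 2 largest falls that met the naming rule belonged to this class, and the deposited tables give no name or function for them. Ranking by fitted change favours abundant genes with 0 reads in the other line, so the place of these 4 genes in this class is no finding in itself. TRINITY_DN11108_c0_g1 had 4029, 2960 and 4165 reads in CCuA replicates 1 to 3, a mean of 282.7 CPM ± 41.9 (SD, n = 3), and 0 reads in every LCuA library, and was thus at least 1332-fold lower in LCuA against a floor of 3 reads per library (edgeR adjusted p = 0.00017). TRINITY_DN14883_c0_g1 had 2199, 1649 and 2203 reads in CCuA, a mean of 153.4 CPM ± 19.5 (SD, n = 3), and 0 in LCuA, at least 723-fold lower (edgeR adjusted p = 0.00017). In the other direction, TRINITY_DN13268_c0_g1 had 1101, 1847 and 1274 reads in LCuA replicates 1 to 3, a mean of 97.9 CPM ± 18.7 (SD, n = 3), and 0 in CCuA, at least 427-fold higher (edgeR adjusted p = 0.00021). TRINITY_DN12771_c0_g1 had 777, 865 and 1360 reads in LCuA, a mean of 70.0 CPM ± 19.2 (SD, n = 3), and 0 in CCuA, at least 306-fold higher (edgeR adjusted p = 0.00033). All 4 genes kept their direction and an adjusted p under 0.05 in each of the 16 other fits that included them, with adjusted p values between 1.1e-30 and 0.0058 (edgeR, DESeq2 or limma-voom). These fits are no independent support, because the genes were chosen from the same libraries as the largest changes. Their position in the genome is not given in the sources used here.

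**Figure D4:**
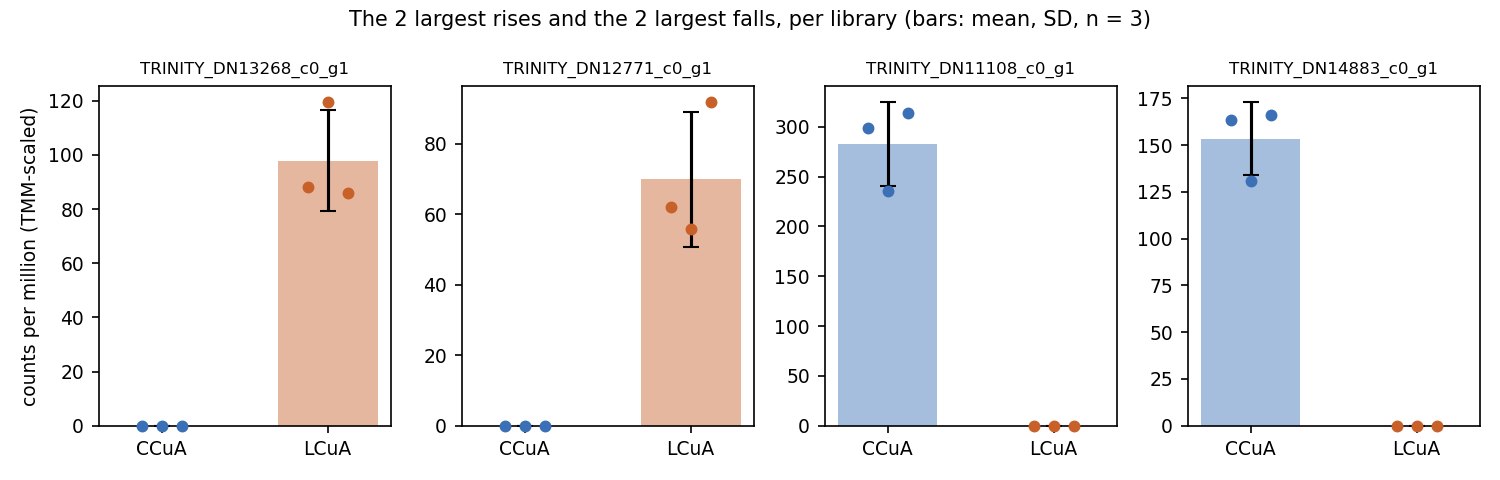
Expression of the 4 named genes in TMM-scaled CPM (y axis, own scale per panel) in CCuA and LCuA; points are libraries, bars are means and error bars are SD (n = 3). The left pair of genes, TRINITY_DN13268_c0_g1 and TRINITY_DN12771_c0_g1, had reads in LCuA and 0 in CCuA, and the right pair, TRINITY_DN11108_c0_g1 and TRINITY_DN14883_c0_g1, had reads in CCuA and 0 in LCuA.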

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

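The sums over assembly components, the fit without the genes read in one line only (3842 calls) and the robust variant of the edgeR fit (4110 calls) were chosen after seeing the data. Directions held in every alternative for the 4 named genes and for all calls that could be refitted. None of the 4127 called genes changed sign under another scaling, filter or tool, the replicate block, or with any library left out. This is no independent support, since the values of the lines did not overlap for 99.95% of the called genes. A change of sign on the same libraries was therefore hardly possible. The number of calls stayed within 1.5 times of 4127 in these fits except without single CCuA libraries, running from 2603 to 4368 when 1 library was left out (1087 to 1825 higher, 1516 to 2543 lower), the highest without LCuA replicate 1. At an adjusted p under 0.01, 1908 genes were called, 777 higher and 1131 lower, of which 1585 differed at least 2-fold, 656 of them higher. A test against a 2-fold change called 909 genes, 428 higher and 481 lower, in place of 2575, because it asks for evidence beyond that fold. DESeq2 called 4981 genes and limma-voom 4134. Summed over assembly components, 3637 of 14972 components were called, 1659 higher and 1978 lower. With at least 20 reads required, 57 genes in place of 87 were seen in CCuA alone. The replicate numbers are not shown to pair the libraries: deviations from the line means correlated at -0.05, 0.04 and 0.18 for replicates 1, 2 and 3, and 2 of the 6 libraries correlated best with their own number. With the replicate block, 3375 genes were called (1457 higher and 1918 lower), 3167 of them also called without it. The planned comparisons on log2 RPKM and the gene list tests, with their alternatives, were not run, for lack of matching column labels and of gene names. A gene that was not called is not shown to be equal in the lines.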

Other observations

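The test of opposite directions in sister genes and the count of components without reads in the other line were chosen after the result was seen; the other tests here were set before their result was seen.

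Where 2 genes of one assembly component were both called, they were mostly called in the same direction; pairs with a member that was not called did not enter this test. Among 540 called genes in 227 components with at least 2 called members, 50 of 446 pairs, or 11.2%, were called in opposite directions, where shuffling the calls among these genes gave a mean of 50.03% and a central 95% range of 45.3% to 54.5%. Without the genes read in one line only the share was 9.5%, and it was 12 of 46, or 26.1%, in pairs that include such a gene, a difference that was not tested. The hypothesis that called sister genes move in opposite directions more often than unrelated genes was not borne out over all pairs. Some pairs did show the pattern of a switch between copies or alleles: 2 CCuA-only genes had a sister read in LCuA alone. Fragments of one transcript, copies under common control and reads divided between similar sequences remain open, and the sequences needed to tell these apart were not analysed here.

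The 202 genes read in one line only are the pattern that most invites a closer look, since they include transcripts of over 1000 reads per library in one line with none in the other. Sampling depth does not account for them: the other 9 splits of the 6 libraries gave at most 5 such genes. For 146 of them the whole component had 0 reads in the other line. Of these, 124 were alone in their component, so they had no sister to divide reads with and the check tested nothing. The other 22 had sisters, and division of reads among sister genes of a component is excluded for them. As the whole cause, such division is also excluded for another 30, whose component sum was still called in the same direction. Division among sisters stays open for 26, whose sisters were read in the other line and whose component sum was not called in that direction. Related sequences in separate components were not tested. Another organism in the cultures could give such genes, although poly(A) selection disfavours bacterial RNA. Medians of the CCuA-only genes varied between CCuA libraries more than in 94.7% of matched random gene lists. For the LCuA-only genes in LCuA this was 59.3%. The rule set in advance for a load that varied between replicates required the SD of the medians to exceed the 95th percentile of the random lists in both lines. That limit was exceeded in neither line, at 0.0660 against 0.0662 in CCuA and 0.0566 against 0.0974 in LCuA. By that rule the outcome counted against a varying load. Because the CCuA value lay so close to its limit, a varying load is nevertheless taken here as neither shown nor excluded, which departs from the rule. Loss of a gene or of its sequence variant in one line, or a complete change in its regulation, also remains open and was not tested.

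LCuA replicate 1 lay apart from LCuA replicates 2 and 3. Lower depth does not account for this: with all libraries thinned to 12326419 reads in 20 draws, its highest correlation with another LCuA library was 0.961, below the 0.972 between the other two. A trend with gene length explained 1.59% of the variance of its deviation (Spearman rho = 0.14 across 17569 genes), so a broad length bias does not account for it either. Without the 100 most abundant genes its higher correlation with another LCuA library was 0.960, still below the 0.971 between the other two. A difference in the state of that culture or in its handling remains open and was not tested.

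Among genes with a recovered length, a length trend does not account for the difference between the lines. The Spearman rho between recovered length and log2 fold change was 0.013 across 17569 genes. A length was recovered for all of the higher and 87.7% of the lower genes. Lengths came from LCuA libraries with at least 10 reads, so lower genes with few LCuA reads, among them all CCuA-only genes, were left out. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split (1 of the 10) called 4127 genes, 2575 of them at least 2-fold, and the highest of the other splits called 0 in both counts by edgeR. Each of the other splits put libraries of both lines into each group. The difference between the lines then added to the spread within the groups, which works against any call. These 0 calls are therefore no measure of what chance gives, and no conclusion is drawn from them.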
